A study of Mus musculus with 9 samples.

How the data were processed

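Circular RNAs (circRNAs, closed loops made when the end of an exon is spliced back to an upstream start) were measured in C2C12 cells, a mouse myoblast line from skeletal muscle. Per the labels, total RNA was taken from proliferating, not yet confluent cells (day 0) and at days 3 and 6 after a switch from medium with fetal bovine serum to medium with less, horse, serum, with 3 libraries per time point and 9 in all. Per the labels, RNA extracted with TRIzol was treated with a bead clean-up kit and a DNase set to enrich circRNAs, and an mRNA-seq kit was used for the libraries. No digestion of linear RNA is named in the sources used here. The labels do not say whether the 3 libraries of a time point came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

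The authors deposited 1 table of raw read counts per circRNA and library, with a locus, a type (exon, intron or intergenic region), a host gene and, for some, a circBase identifier. Per the submitters' processing notes, BWA was used with the mouse build GRCm38.p4 (mm10). The circRNA caller, versions, filters and the handling of duplicate reads are not given in the sources used here. The counts are whole numbers, and the smallest above 0 is 2, so circRNAs with 1 read in a library are listed there at 0. The table holds no linear reads, so the planned test of the circular fraction was not run. Every column of counts was mapped to a sample by its name. As a check of the build, 86.8% of circRNA starts and 86.8% of ends lay at an exon edge of the GENCODE M21 annotation of GRCm38 at an offset of 0 bp, against 0.283% and 0.188% at an offset of -1 bp and 0.183% and 0.299% at an offset of 1 bp. Coordinates are given as deposited, counted from 1. Gene symbols were taken from that annotation through the deposited Ensembl identifiers, and exon numbers from the annotated transcript that holds both ends. Back-splice reads are assigned to a host by its locus, and 113 circRNAs (0.308% of those with a host) lay on the strand opposite to the named host.

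The totals of back-splice reads were 208787 to 443955 per library. With PCR reads and no molecular identifiers, reads are not independent molecules, so intervals and floors cover counting error only. The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) on the counts as deposited, with TMM factors on the total reads of each library, a filter of filterByExpr (minimum count 5, minimum total 15), group means and no block. All 9 libraries entered each fit, which left 6 residual degrees of freedom, and adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The filter kept 8153 of 37751 circRNAs with 86.2% of reads. The same test was run on counts summed over all circRNAs of a host gene, for 4135 of 6943 hosts with 97.4% of reads. Levels are in CPM, reads scaled to a common library total by the TMM-adjusted totals, as mean ± SD of 3 libraries. Log2 fold changes (prior count 0.125) carry an approximate standard error (SE), as edgeR reports none. It is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Where all libraries of a group were at 0, the fold is given as a lower bound against a floor of 3 reads per library, and no fitted value is printed for it. If a molecule gives several reads, a group at 0 may stand for more than 3 reads per library. The true fold can then lie below the printed bound. Of values where 10 to 20 reads were expected, 33.5% were 0. No reads means none listed, as single reads appear as 0.

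Before the data were examined, 14 gene lists were fixed: sarcomere, calcium handling and excitation-contraction coupling, myogenic regulators and fusion, dystrophin complex with costamere and membrane, muscle energy metabolism, cell cycle and mitosis, DNA replication and repair, chromatin modifiers, ubiquitin ligases, splicing factors and other RNA-binding proteins of circRNA biogenesis, extracellular matrix, quiescent or reserve cells, adipocyte or osteoblast markers, and hosts of circRNAs described in muscle. The last list shares 7 of its 17 tested hosts with other lists. Lists were tested on host counts with camera (limma 3.58.1, preset correlation 0.01), adjusted over all 42 tests of 14 lists by 3 comparisons, and again with an estimated correlation. A second planned test, fry, was used in its directional form. It asks whether a list shifted up or down as a whole, and not whether it changed more than other hosts. Lists are said to pass by camera unless fry is named. The numbers of circRNAs and reads per library were compared with exact two-sided permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. The overlap of the comparisons that share the day 0 libraries was set beside 20 simulations of unchanged groups, drawn around the observed day 0 means.

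The names in the text follow a rule fixed before the data were examined. Per comparison with day 0, it takes the 7 largest increases and 7 largest decreases among circRNAs past the threshold whose libraries do not overlap between groups and whose higher group averages at least 10 reads, and 4 and 4 between days 6 and 3. For hosts it takes 6 and 6, and the 3 hosts of each list with the smallest p at day 6 against day 0. It adds the leading circRNA of Zfp609, Qk, Bnc2, Hipk3, Cdyl and Zfp292, the 10 most abundant circRNAs and the 5 hosts with the most circRNAs. Members of a fixed list that passed the threshold outside this rule, and Zfp516, were named after their values were seen, and 1 such member is not reported here. circRNAs are named by host and coordinates, and were not matched to circRNAs known by name.

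The alternatives were DESeq2 1.42.0, library size without TMM factors, upper-quartile factors, a minimum count of 10, no filter, a fit of only the 2 groups compared, a replicate block, a minimum fold of 2, and leaving out each library in turn. The filter was applied anew in the fits of 2 groups, of thinned reads and without a library, so that the features tested also differ there. After the data were seen, 2 were added: thinning all libraries to the smallest total of 208787 reads, and dividing reads by the median count of circRNAs found in that library alone, as an estimate of reads per molecule.

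The tests were tested on simulated data drawn from the means, dispersions and library sizes of these samples, with 200 features changed at day 6. The changed features were drawn only from those with the most reads on average, 2324 circRNAs and 1982 hosts. Features with fewer reads were not changed, so the shares below say nothing about them. For day 6 against day 0, 40.9% of 8-fold, 20.9% of 4-fold and 1.49% of 2-fold changes were recovered among 5316 circRNAs, with 0 false calls. Among 3312 hosts, 57.6%, 40.3% and 2.99% were recovered, with 3 false calls. For day 6 against day 3 the shares were 39.4%, 25.4% and 2.99% with 6 false calls for circRNAs, and 56.1%, 47.8% and 5.97% with 2 false calls for hosts. Most 2-fold changes were therefore not detectable at this depth and spread, even among the features with the most reads. Annotation and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.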

Results

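Reads across back-splice junctions of circRNAs were counted in 9 libraries of C2C12 mouse myoblasts, to follow circRNA expression at 3 time points of differentiation. Proliferating cells (day 0) gave totals of 317159, 230183 and 263833 back-splice reads in replicates 1, 2 and 3. The day 3 libraries held 320622, 297409 and 353680 reads, and the day 6 libraries 208787, 243471 and 443955. Mean totals were 270392 ± 43857 at day 0, 323904 ± 28279 at day 3 and 298738 ± 126952 at day 6 (SD, n = 3 each). The log2 ratio of day 3 to day 0 was 0.26, above the pooled SD of 0.19, and those of day 6 to day 0 and to day 3 were 0.14 and -0.12, within pooled SDs of 0.44 and 0.42. Two-sided exact permutation tests gave p = 0.2 for day 3 against day 0 and 0.9 for both other pairs, where 0.1 is the smallest p possible. Libraries listed 9480 ± 1860, 9743 ± 132 and 8798 ± 1773 circRNAs at days 0, 3 and 6 (SD, n = 3), with exact permutation p = 1, 0.7 and 0.4 for day 3 against day 0, day 6 against day 0 and day 6 against day 3. No columns were identical, and libraries of the same day differed by more than sampling noise, with a chi-square of 11.7 to 14.6 per degree of freedom.

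The table listed 37751 circRNAs from 6943 host genes. Exonic circRNAs made up 33054 of them (87.6%) and 95.4% of reads, intronic ones 3761 (9.96%) and 3.65% of reads, and intergenic ones 936 (2.48%) and 0.927% of reads. The hosts with the most distinct circRNAs were Fn1 (102), which encodes fibronectin, Arhgap10 (81), Utrn (79), which encodes the dystrophin homologue utrophin, Ttn (79), which encodes the giant sarcomere protein titin, and Asap1 (66). In at least 2 libraries there were 16, 44, 32, 24 and 31 of these. Fn1 held 1403 reads in all, against 27574 for Arhgap10. Most circRNAs were listed in 1 library: 23182 (61.4%), which held 8.26% of reads. The 1490 circRNAs listed in all 9 libraries (3.95%) held 60.2% of reads. Both ends lay at annotated exon edges for 72.9% of single-library circRNAs (Wilson 95% interval 72.4 to 73.5) and for 94.4% of those in all libraries (93.1 to 95.5).

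**Figure D1:**
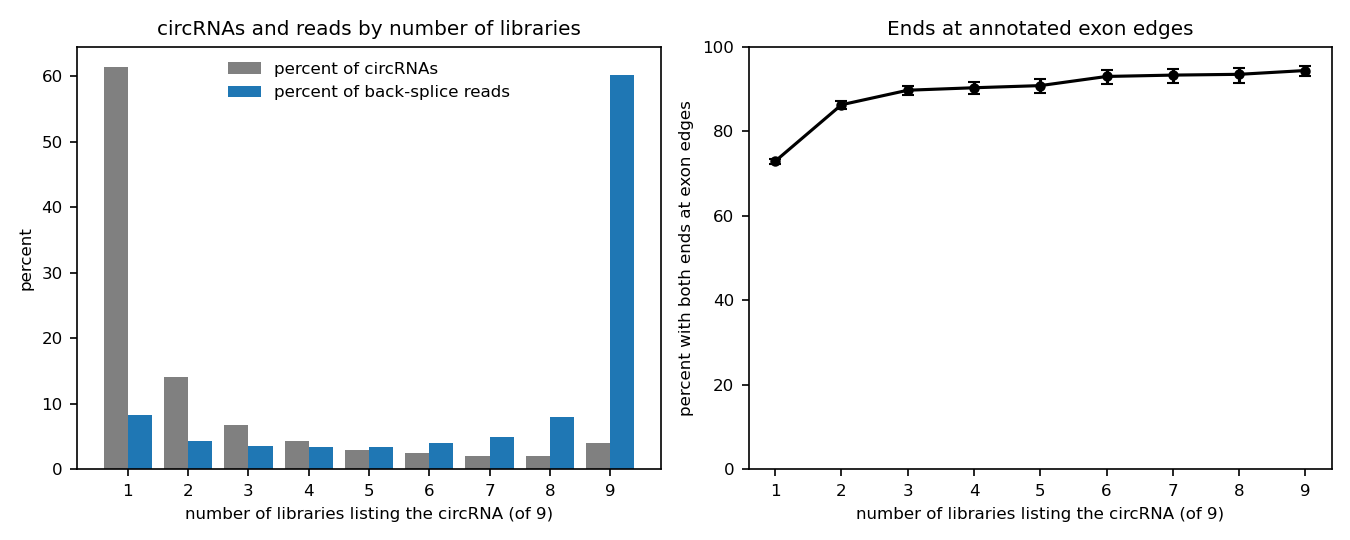
Left, percent of circRNAs (grey bars) and of back-splice reads (blue bars) by the number of libraries that list a circRNA, with 61.4% of circRNAs in 1 library and 60.2% of reads in circRNAs of all 9. Right, percent of circRNAs with both ends at annotated exon edges by the same number, points with Wilson 95% intervals, from 72.9% to 94.4%.

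Day 3 was compared with day 0 to find circRNAs that differed between proliferating and differentiating cells. A circRNA of exons 123 to 127 of Ttn (2:76853605-76856366, minus strand) rose from 23.1 ± 20.2 to 6288 ± 844 CPM, a log2 fold change of 8.03 ± 0.33 (SE, edgeR adjusted p = 2.5e-27). Another 7 circRNAs had no reads at day 0 and were among the largest increases. A circRNA of exons 3 to 5 of the cholesterol transporter gene Abca1 (4:53127597-53133015) reached 294 ± 50.3 CPM, at least 26.9-fold higher. Ttn circRNAs of exons 139 to 147 (2:76841768-76847808) and 123 to 125 (2:76854150-76856366) were at least 20.6-fold and 20.4-fold higher. An intronic circRNA of the transcriptional repressor gene Etv6 (6:134062064-134066465) was at least 19.8-fold higher, an intronic circRNA of the calcium release channel gene Ryr1 (7:29035962-29040893) at least 18.5-fold. A circRNA of exons 12 to 16 of Ap3d1 (10:80715871-80719812), a subunit gene of the adaptor complex AP-3, was at least 18.1-fold higher. The remaining one, 2:77074836-77173607, was deposited as intergenic and was at least 16.1-fold higher. It starts at an exon edge of Ccdc141 and ends 2971 bp beyond that gene. In a fit of only these 2 groups the circRNAs of Ap3d1 and 2:77074836-77173607 did not pass the threshold.

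Decreases at day 3 included circRNAs of Spag5, Gstcd and Knl1. A circRNA of exons 17 to 23 of Spag5 (11:78319986-78321766), which encodes a mitotic spindle protein, fell from 3346 ± 410 to 693 ± 295 CPM, a log2 fold change of -2.27 ± 0.26 (edgeR adjusted p = 6.3e-09). The circRNA of Gstcd exons 2 to 5 (3:133062566-133085025) changed by -2.75 ± 0.41 log2 and that of the kinetochore gene Knl1, exons 10 to 13 (2:119076936-119086650), by -2.57 ± 0.63. The Knl1 circRNA did not pass with DESeq2, with a minimum count of 10 or in a fit of only these 2 groups, and was at -3.47 without day 3 replicate 2. The circRNA of Racgap1 (15:99628634-99637774), a cytokinesis gene, was at least 20.1-fold lower, but did not pass without day 0 replicate 1 or 3 (edgeR adjusted p = 0.0714 and 0.0576), with DESeq2 or with a minimum count of 10. That of Spop (11:95470522-95474612), an adaptor gene of a ubiquitin ligase, was at least 14.7-fold lower and did not pass without day 0 replicate 2 or 3 or any 1 day 3 library (adjusted p of 0.0537 to 0.0803). The circRNA of Zbtb38 (9:96718210-96752573) changed by -2.69 ± 0.61 log2 and did not pass without day 0 replicate 2 or 3 or day 3 replicate 1 or 2 (0.0664 to 0.183), with log2 fold changes of -2.45 to -2.61, or with no filter. The circRNA of exons 2 and 3 of Ezh2 (6:47576536-47577667), the gene of a histone methyltransferase, changed by -1.97 ± 0.43 log2 and did not pass without day 3 replicate 1 (0.0550). Neither the Spop nor the Ezh2 circRNA passed in a fit of only these 2 groups.

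Of 8153 circRNAs tested, 107 were higher and 22 lower at day 3 (edgeR), from 112 host genes. The libraries of the groups did not overlap for 122 of these 129, which selection by the test itself favours, and chance gives 10% among circRNAs not selected by it. DESeq2 called 272 (170 higher, 102 lower), a fit of only these 2 groups 30 (21 higher, 9 lower), and reads divided by an estimate of reads per molecule 138, of which 70.3% were higher against 82.9% in the first count. The median log2 fold change of all tested circRNAs was 0.12 with TMM factors and -0.01 with DESeq2, and that of all hosts was -0.02 with TMM, -0.15 by library size and -0.13 with DESeq2, so that changes are relative to these scalings.

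**Figure D2:**
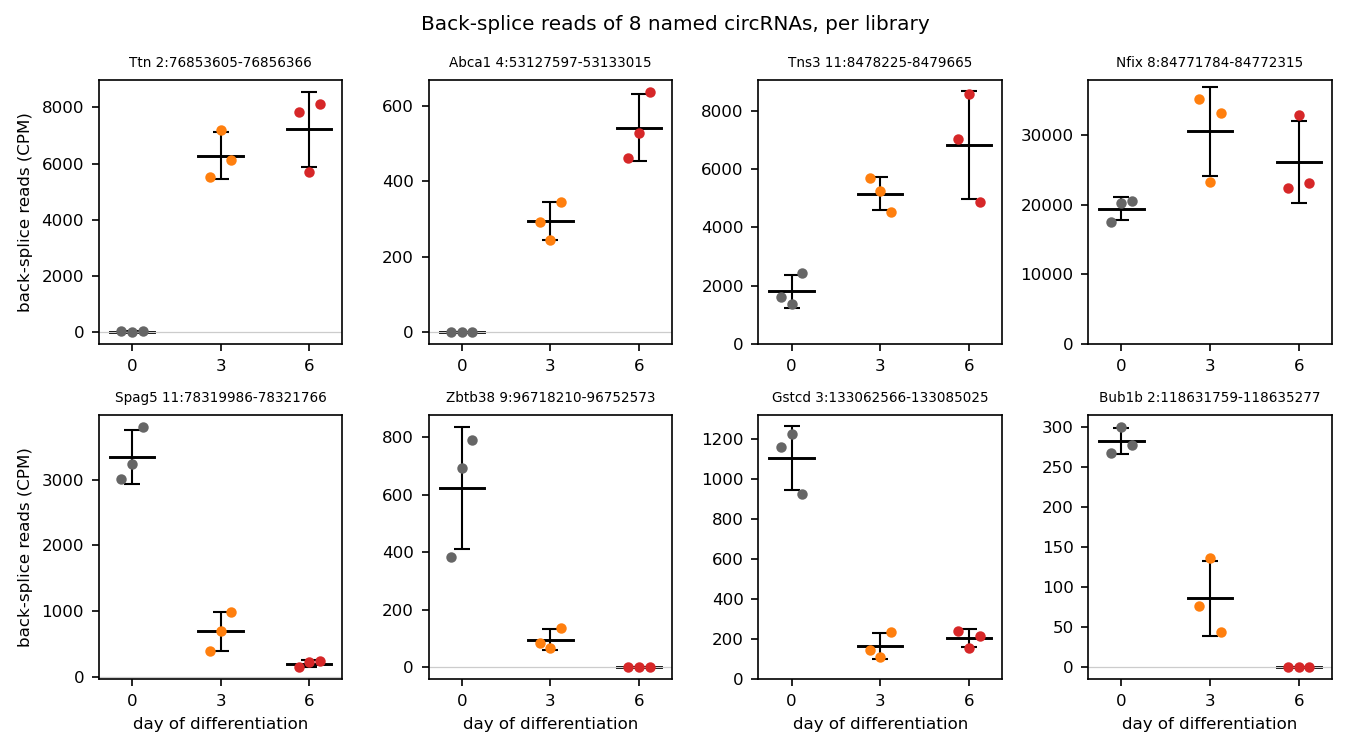
Back-splice reads in CPM (y axis, linear, one scale per panel) by day (x axis) for 8 named circRNAs; points are libraries, lines means and bars SD of 3 libraries. The Ttn circRNA rose from 23.1 to 6288 and 7222 CPM, and the Spag5 circRNA fell from 3346 to 693 and 202 CPM.

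Summed per host gene, the lists of sarcomere and calcium handling hosts were higher at day 3. Among 22 tested sarcomere hosts, Ttn and Tnnt1, the slow skeletal troponin T gene, rose. Ttn went from 37.2 ± 38.0 to 7537 ± 753 CPM (log2 fold change 7.64 ± 0.38, edgeR adjusted p = 1.9e-17) and Tnnt1 from 3.80 ± 6.58 to 230 ± 77.6 CPM (5.84 ± 0.93, 4.3e-05). Without day 0 replicate 3 the log2 fold change of Ttn was 8.56 and Tnnt1 was at least 22.1-fold higher, and without day 0 replicate 1 that of Tnnt1 was 5.20. The list was higher as a whole (mean log2 fold change 3.31, median 4.38, camera adjusted p = 9.8e-05), and 2 hosts rose when adjusted over the list alone. Because 10 of its hosts had no reads in 1 group, the median was 0.82 with these at their bounds. Of 20 hosts of calcium handling, Ryr1 rose from 232 ± 126 to 2401 ± 304 CPM (3.36 ± 0.27, 2.6e-11), as did 1 when adjusted over the list alone, and the list mean was 1.24 (median 0.77, camera adjusted p = 8.0e-04), or 1.93 and 2.12 without day 0 replicates 1 and 3. Of 35 hosts of myogenic regulators and fusion, 5 rose, and 6 when adjusted over the list alone: Dysf, the membrane repair gene dysferlin (2.59 ± 0.31), Mef2a, a muscle transcription factor gene (1.57 ± 0.26), Celf2 (2.74 ± 0.44, or 3.49 without day 0 replicate 3), Nfix and Elmo1, which did not pass with DESeq2 or in a fit of only these 2 groups. The mean of that list was 0.15 (median 0.12, camera adjusted p = 0.016), with an adjusted p = 0.086 with an estimated correlation. It did not pass with a replicate block (mean 0.17, adjusted p = 0.053) or without day 0 replicate 1 (0.24, adjusted p = 0.051), and its mean was -0.06 without day 3 replicate 2 and 0.24 to 0.50 without any 1 other library except day 6 replicate 3. Of 28 hosts of the dystrophin complex and membrane, Utrn (1.35 ± 0.15, edgeR adjusted p = 5.5e-08) and Lrp4, a gene of the neuromuscular junction (2.88 ± 0.26, 5.9e-10), rose, and 4 did when adjusted over the list alone. The list as a whole did not pass (mean 0.07, median 0.20, camera adjusted p = 0.280), but did with fry (adjusted p = 0.018).

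Hosts of cell cycle and mitosis were lower at day 3. Of 36 tested, 6 fell, and 6 when adjusted over the list alone: Diaph3, a formin gene (-2.03 ± 0.30, edgeR adjusted p = 1.0e-05), Espl1, which encodes separase (-1.84 ± 0.31, 1.2e-04), Knl1 (-1.94 ± 0.34, 1.8e-04), Racgap1, Cit and Bub1b. Racgap1 did not pass without day 0 replicate 1 or 3 or day 3 replicate 1 (0.0934 to 0.145). Bub1b did not pass without day 0 replicate 2 or 3 or day 3 replicate 3 (0.112 to 0.151) or with thinned reads. Neither passed with DESeq2, upper-quartile factors or a minimum count of 10. The list mean was -2.19 and the median -1.82 (camera adjusted p = 4.1e-11). Of 40 hosts of DNA replication and repair, Topbp1, a checkpoint gene (-3.19 ± 0.87, 0.026), and Rad18, a ubiquitin ligase gene of DNA repair (-4.53 ± 1.35, 0.048), fell, and 4 did when adjusted over the list alone. The list mean was -1.66 (median -1.53, or -1.33 with the 6 hosts without reads in a group at their bounds, camera adjusted p = 6.4e-05), and the mean was -2.73 without day 3 replicate 2. Topbp1 did not pass without day 0 replicate 2 or 3 or day 3 replicate 3 (0.0658 to 0.103), or in a fit of only these 2 groups, and was at -4.13 and -2.60 without day 3 replicates 1 and 3. Rad18 did not pass without day 0 replicate 3 (log2 fold change -3.17, adjusted p = 0.594) or day 3 replicate 1 (0.110), nor with DESeq2, upper-quartile factors, a minimum count of 10 or only these 2 groups. With an estimated correlation the lists of the sarcomere, calcium handling, cell cycle and DNA replication passed as well (adjusted p = 0.024, 0.038, 0.0037 and 0.024).

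Other hosts were among the largest changes at day 3. Pkhd1, which encodes the cilium protein fibrocystin, had no reads at day 0 and 154 ± 45.3 CPM at day 3, at least 14.3-fold higher, while Exoc1, of the exocyst, was at least 15.4-fold (at least 9.65-fold without day 3 replicate 1) and Insc at least 11.2-fold higher. Insc did not pass in a fit of only these 2 groups. Raly, at least 14.2-fold higher, did not pass without day 0 replicate 2 or 3 or day 3 replicate 3 (edgeR adjusted p of 0.0621 to 0.0780), and Lpin1, a phosphatidate phosphatase gene at least 10.5-fold higher, did not pass without any 1 day 0 library or without day 3 replicate 1 or 3 (0.0633 to 0.0863), nor with a minimum count of 10, only these 2 groups or thinned reads. Gstcd (-2.57 ± 0.37) and Mtbp (-3.10 ± 0.57) fell. Haus6, a gene of the spindle complex augmin (-3.27 ± 0.96), did not pass without any 1 of the day 0 or day 3 libraries (0.0602 to 0.329), with no filter or with a replicate block, and Myo19, at least 15.8-fold lower, did not pass without day 0 replicate 2 (0.125). In all, 126 of 4135 hosts were higher and 37 lower (edgeR), and the groups did not overlap for 161 of these 163, which selection by the test favours (10% by chance among hosts not selected by it). DESeq2 called 286 hosts (169 higher, 117 lower). The share of increases was 77.3% with TMM factors, 67.1% by library size, 59.1% with DESeq2 and 59.6% after division by reads per molecule.

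Day 6 was compared with day 0 to show which differences were present at the later time of differentiation. The Ttn circRNA of exons 123 to 127 was at 7222 ± 1329 CPM (log2 fold change 8.23 ± 0.34, edgeR adjusted p = 1.0e-27). The Abca1 circRNA at 4:53127597-53133015 reached 542 ± 88.0 CPM, at least 49.5-fold above day 0, that of Ap3d1 was at least 41.1-fold higher, the Ttn circRNA of exons 123 to 125 at least 30.8-fold and the Etv6 circRNA at least 26.2-fold. An intronic circRNA of Gm13483 (2:50355025-50406520) was at least 27.1-fold higher. A circRNA of exons 2 and 3 of Nos1 (5:117866839-117879410), the neuronal nitric oxide synthase gene, was at least 25.4-fold higher, and one of exons 2 and 3 of Fam53b (7:132771578-132779385) at least 25.1-fold. The Spag5 circRNA fell further from the day 0 level, to 202 ± 46.8 CPM (-4.04 ± 0.29, 1.5e-16).

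At day 6 some circRNAs found in all day 0 libraries had no reads. The Zbtb38 circRNA, at 623 ± 213 CPM at day 0, was at least 57.1-fold lower, that of exons 17 to 19 of the spindle checkpoint gene Bub1b (2:118631759-118635277) at least 25.9-fold. That of exons 12 to 15 of the hyaluronan receptor gene Cd44 (2:102831330-102837938) was at least 20.9-fold lower and that of exons 21 to 25 of the DNA repair gene Fanci (7:79433183-79438400) at least 20.9-fold lower. The circRNA of exons 19 to 22 of Kif14 (1:136502647-136513822), a mitotic kinesin gene, was at least 19.7-fold lower and did not pass without day 0 replicate 1 (edgeR adjusted p = 0.0575). That of exons 3 to 7 of the nuclear pore gene Nup43 (10:7669553-7676362), at least 12.6-fold lower, did not pass without day 0 replicate 3 or any 1 day 6 library (0.0588 to 0.176), with a replicate block or in a fit of only these 2 groups. That of exons 2 to 4 of Creb1 (1:64550849-64559768), at least 11.7-fold lower, did not pass without day 0 replicate 1 or 3, day 3 replicate 1 or any 1 day 6 library (0.0799 to 0.121), nor with a minimum count of 10, no filter, only these 2 groups, a replicate block or reads divided by reads per molecule. At day 6, 120 circRNAs were higher and 42 lower than at day 0 (edgeR), from 136 hosts, and the groups did not overlap for 161 of these 162, which selection by the test favours (10% by chance among circRNAs not selected by it). DESeq2 called 466 (272 higher, 194 lower), which moved the share of increases from 74.1% to 58.4%, and a fit of only these 2 groups called 70 (46 higher, 24 lower).

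Hosts of the sarcomere and of calcium handling were higher at day 6. Ttn reached 9202 ± 1468 CPM (log2 fold change 7.93 ± 0.38, edgeR adjusted p = 7.7e-18) and Tnnt1 343 ± 55.5 CPM (6.41 ± 0.94, 7.0e-06), the 2 of 22 sarcomere hosts that passed; adjusted over the list alone, 4 were higher and 1 lower. Without day 0 replicate 3 the log2 fold change of Ttn was 8.85 and Tnnt1 was at least 33.1-fold higher, and without day 0 replicate 1 that of Tnnt1 was 5.77. The list mean was 3.01 and the median 4.87, or 0.62 with 12 hosts at their bounds (camera adjusted p = 3.6e-04). Of 20 hosts of calcium handling, 3 rose, and 3 when adjusted over the list alone: Ryr1 to 3668 ± 688 CPM (3.97 ± 0.27, 3.5e-13), Pde4dip (1.18 ± 0.26, 0.0024) and the calcium channel gene Ryr3 (1.76 ± 0.54, 0.047). Ryr3 did not pass by library size, with other filters, with a replicate block, in a fit of only these 2 groups, without any 1 day 0 library, or without day 3 replicate 1 or day 6 replicate 2 or 3 (0.0679 to 0.194). The mean of the list was 1.46 (median 1.03, camera adjusted p = 1.2e-04). Of 35 hosts of myogenic regulators and fusion, 7 rose, and 8 when adjusted over the list alone: Dysf (3.14 ± 0.31, 2.3e-09), Mef2a (1.92 ± 0.27, 2.3e-06), Celf2 (2.88 ± 0.44, 1.6e-05, or 3.63 without day 0 replicate 3), Nfix, Elmo1, Bin1 and Myof. Myof did not pass without day 0 replicate 2 or 3 or day 6 replicate 3 (0.0525 to 0.0776). Bin1 (2.56 ± 0.64, or 4.22 without day 0 replicate 2) did not pass without day 0 replicate 3 (0.0509), and neither it nor Elmo1 did in a fit of only these 2 groups. Nfix did not pass without day 6 replicate 2 (0.0976), with DESeq2, by library size, with a minimum count of 10 or in a fit of only these 2 groups. Their list had a mean of 0.26 and a median of 0.10 (camera adjusted p = 0.012), with an adjusted p = 0.083 with an estimated correlation, and its mean was -0.14 without day 6 replicate 3 and 0.39 to 0.65 without any 1 day 0 library, day 3 replicate 1 or 3, or day 6 replicate 1. Of 28 hosts of the dystrophin complex and membrane, 4 rose: Lrp4 to 2955 ± 128 CPM (3.45 ± 0.27, 3.6e-12), Utrn to 7589 ± 233 CPM (1.58 ± 0.15, 9.9e-10), Svil and Ahnak. Adjusted over the list alone, 6 were higher and 1 lower, with a list mean of 0.90 (median 0.86, camera adjusted p = 0.0049), which was 1.42 without day 0 replicate 3 and 0.33 without day 6 replicate 2. Svil, the supervillin gene (1.65 ± 0.48), did not pass without day 0 replicate 2 or day 6 replicate 2 (0.131 and 0.198), and Ahnak (1.75 ± 0.50) did not pass without day 0 replicate 2 or 3 or day 6 replicate 1 (0.0758 to 0.372). Neither passed in a fit of only these 2 groups.

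Hosts of cell division were lower at day 6 than at day 0. Of 36 hosts of cell cycle and mitosis, 10 fell, and 17 when adjusted over the list alone. Espl1 fell from 1672 ± 118 to 224 ± 130 CPM (-2.92 ± 0.33, edgeR adjusted p = 4.6e-08), and Diaph3 changed by -2.71 ± 0.31 (4.8e-08) and Knl1 by -2.74 ± 0.35 (6.9e-07). Kif14 was at least 20.6-fold lower, and the others were Racgap1, Cep192, Lmnb1, Cit, Zwilch and Bub1b. Cep192 did not pass without day 0 replicate 3 or day 6 replicate 2 or 3 (0.0715 to 0.0738), and Lmnb1 and Zwilch did not in a fit of only these 2 groups. The list mean was -3.88 and the median -3.19, or -2.72 with 11 hosts at their bounds (camera adjusted p = 2.0e-14). Of 40 hosts of DNA replication and repair, 6 fell, and 9 when adjusted over the list alone. The list had a mean of -2.65 and a median of -2.40, or -2.15 with 10 hosts at their bounds (camera adjusted p = 2.8e-06). They were Topbp1 (-3.81 ± 0.90, 0.0054), Fanci (-4.89 ± 1.20, 0.0077), Timeless (-6.21 ± 1.53, 0.0077), Uhrf1, Bard1 and Rrm1. Rrm1 did not pass without any 1 of the 9 libraries (0.0584 to 0.361), with upper-quartile factors, no filter, a replicate block or only these 2 groups. Bard1 did not pass without day 0 replicate 2 or 3 (0.101 and 0.0815), with DESeq2, a minimum count of 10 or only these 2 groups. Fanci did not pass without day 0 replicate 2 (0.0996) or in a fit of only these 2 groups, and Timeless, a replication fork gene, did not pass without day 0 replicate 3 (0.0741). Without day 6 replicate 3 Fanci and Timeless changed by -4.24 and -5.54, and without day 6 replicate 2 Timeless was at least 20.7-fold lower. Uhrf1, the gene of a factor of maintenance DNA methylation, was at least 12.5-fold lower and did not pass without day 0 replicate 3 or any 1 day 6 library (0.0546 to 0.381; at least 4.24-fold lower without day 0 replicate 3), nor with a minimum count of 10, a replicate block, only these 2 groups or thinned reads. With an estimated correlation the sarcomere, calcium handling, dystrophin, cell cycle and DNA replication lists passed at day 6 (adjusted p = 0.024, 0.024, 0.048, 0.0033 and 0.024).

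**Figure D3:**
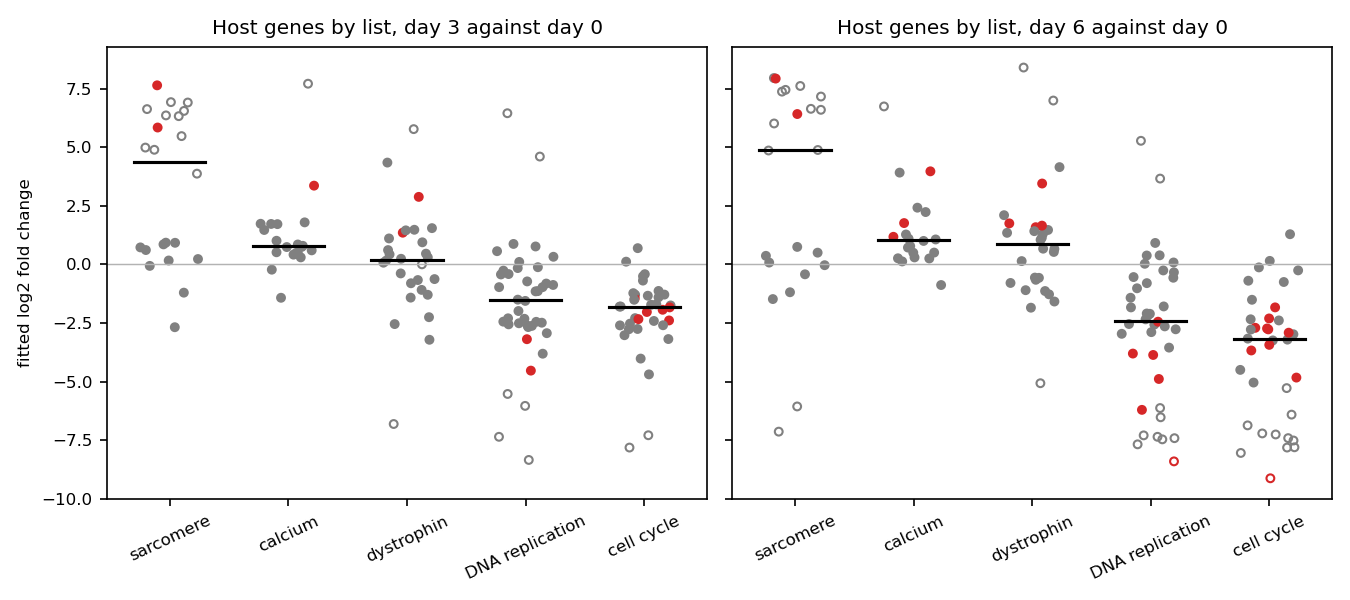
Fitted log2 fold change of back-splice reads per host (y axis) for 5 gene lists (x axis) at day 3 (left) and day 6 (right) against day 0; each point is a host, red past the adjusted threshold of 0.05, open where a group had no reads (the fitted value is then no measured fold), and black lines are medians of fitted values. Cell cycle hosts had medians of -1.82 at day 3 and -3.19 at day 6.

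Among the other hosts at day 6, Pkhd1 was at 941 ± 181 CPM, at least 87.8-fold above day 0. Nos1 was higher at least 30.1-fold, Exoc1 at least 24.1-fold, Filip1 at least 21.9-fold, Cdh23, a cadherin gene, at least 13.9-fold and Insc at least 13.4-fold (7.24-fold without day 6 replicate 1). Spag5 fell (-3.96 ± 0.29, edgeR adjusted p = 1.1e-12) and Igsf5 was at least 27.6-fold lower. Cttn, the cortactin gene, at least 13.7-fold lower, did not pass without any 1 day 0 library (0.0692 at the highest) or with DESeq2. Dock8, at least 13.6-fold lower, was at least 5.0-fold lower without day 0 replicate 2 and did not pass then (0.267), and Ncoa5, at least 12.8-fold lower, did not pass without any 1 day 0 or day 6 library (0.0581 to 0.116) or with a minimum count of 10. In all, 159 hosts were higher and 74 lower (edgeR), and the groups did not overlap for 230 of these 233, which selection by the test favours (10% by chance among hosts not selected by it). Without day 0 replicate 3, 42 hosts were lower and the share of increases was 78.4%. DESeq2 called 460 hosts (246 higher, 214 lower) and a fit of only these 2 groups 139. The share of increases was 68.2% with TMM factors, 57.6% by library size, 53.5% with DESeq2 and 55.6% after division by reads per molecule. The median of all hosts was -0.13 with TMM and -0.24 by library size.

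Day 6 was compared with day 3 to show changes between the times of differentiation. The Spag5 circRNA fell from 693 ± 295 to 202 ± 46.8 CPM (log2 fold change -1.77 ± 0.26, edgeR adjusted p = 3.9e-05). The Cd44, Zbtb38 and Bub1b circRNAs had reads in all day 3 libraries and none at day 6, and were at least 9.02-fold, 8.79-fold and 7.87-fold lower (adjusted p = 0.014, 1.1e-05 and 0.0094). A circRNA of exon 2 of Zfp516 (18:82955524-82957449), a zinc finger gene, fell from 3051 ± 354 to 1743 ± 273 CPM (-0.81 ± 0.17, 0.014). Of the hosts, Pkhd1 rose from 154 ± 45.3 to 941 ± 181 CPM (2.61 ± 0.43, 0.0018), Spag5 fell (-1.76 ± 0.27, 6.4e-04) and Igsf5 was at least 6.49-fold lower (0.015). In total 0 circRNAs were higher and 5 lower with edgeR, where 354 had an unadjusted p below 0.05 and DESeq2 called 20 (3 higher, 17 lower). For hosts 1 was higher and 2 lower, where 246 had an unadjusted p below 0.05 and DESeq2 called 19 (9 higher, 10 lower). The groups did not overlap for any of the 5 circRNAs and 3 hosts, which selection by the test favours (10% by chance among features not selected by it). A fit of only these 2 groups called 0 circRNAs and 1 host (edgeR). Dividing by reads per molecule gave 2 circRNAs, 1 higher and 1 lower, and only 1 of them was among the 5. The Cd44 circRNA did not pass without day 6 replicate 3 (0.0709), and Igsf5 did not pass without day 0 replicate 1 or 3 (0.0559 and 0.144). The Zfp516 circRNA did not pass without day 6 replicate 1 or with a minimum fold of 2. Without day 3 replicate 2 the count of circRNAs was 8, and without day 6 replicate 1, 2 or 3 that of hosts was 8, 6 and 7.

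Between days 3 and 6 the lists of the cell cycle, the dystrophin complex and DNA replication passed, with 0 members called among all hosts (edgeR; 246 of 4135 hosts at an unadjusted p below 0.05, DESeq2 19 adjusted calls). Cell cycle hosts had a mean log2 fold change of -1.69 and a median of -1.23, or -0.56 with 12 hosts at their bounds (camera adjusted p = 1.2e-04, and adjusted p = 0.024 with an estimated correlation), and 3 fell when adjusted over the list alone. Their mean was -0.84 without day 3 replicate 1 (adjusted p = 0.0053) and -0.93 after division by reads per molecule. Dystrophin complex hosts had a mean of 0.83, or 0.37 without day 6 replicate 2, and a median of 0.32 (camera adjusted p = 0.0049), with an adjusted p = 0.066 with an estimated correlation and 0 hosts past the threshold when adjusted over the list alone. DNA replication hosts had a mean of -0.996 and a median of -0.60, or -0.33 with 11 hosts at their bounds (camera adjusted p = 0.044), with an adjusted p = 0.168 with an estimated correlation and 0 hosts when adjusted over the list alone. With fry the DNA replication list did not pass (adjusted p = 0.120). That list did not pass with a replicate block (mean -1.02, adjusted p = 0.055), after division by reads per molecule (-0.57, adjusted p = 0.150) or without any 1 library other than day 3 replicate 3, and without day 3 replicate 2 its mean was 0.03 (adjusted p = 0.781). Without day 0 replicate 1 or 2, day 3 replicate 1 or 3, or day 6 replicate 1 it was between -0.66 and -0.36. The sarcomere, calcium handling and myogenic lists did not pass (camera adjusted p = 0.845, 0.206 and 0.646), with 0 hosts past the threshold in each, and the sarcomere list had a mean of -0.30, a median of 0.04 and a test upward.

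Both comparisons with day 0 share its 3 libraries. Of 129 circRNAs called at day 3 and 162 at day 6, 109 were called at both in the same direction (91 higher, 18 lower) and 0 in opposite directions (edgeR). Independent lists of these sizes would share 1.57 higher and 0.113 lower circRNAs, and 20 simulations of unchanged groups against the same day 0 libraries shared 0. This 0 comes from groups without effects, and does not measure what shared controls add among called circRNAs. The simulated groups were drawn around the observed day 0 means, so the error of these means did not enter the simulated values. Among hosts, 136 were called at both (109 higher, 27 lower), against 4.84 and 0.662 for independent lists and 0 in the simulations. The covariance of the log2 fold changes across circRNAs was 5.75 against 0.0973 simulated, a difference of 5.65. Across hosts it was 3.62 against 0.118, a difference of 3.51. As the error of the day 0 means is left out of the simulations, these differences still hold what the shared libraries add. With 3 control libraries no split into parts of at least 2 was possible, and part of the excess over these values can come from the shared controls.

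The most abundant circRNA was exon 2 of Nfix (8:84771784-84772315), the gene of a transcription factor of fetal myogenesis, at 19450 ± 1668, 30489 ± 6407 and 26107 ± 5854 CPM at days 0, 3 and 6 (log2 fold changes against day 0 of 0.65 ± 0.09 and 0.42 ± 0.09). It did not pass at either day with DESeq2, in a fit of only the 2 groups compared, or after division by reads per molecule. Of the others among the 10 most abundant, those of Tns3, the tensin 3 gene (11:8478225-8479665; 1.51 ± 0.17 and 1.91 ± 0.17), Rad52, a recombination gene (6:119920110-119921028; 1.23 ± 0.14 and 1.13 ± 0.14), Gigyf2 (1:87364104-87380008; 0.68 ± 0.10 and 0.92 ± 0.10) and Cnot6l, a deadenylase gene (5:96128943-96134132; 0.48 ± 0.10 and 0.54 ± 0.10), rose at both days. That of Nfkb1 (3:135655500-135669339; -0.40 ± 0.10 and -0.44 ± 0.10) fell at both. The Nfkb1 and Cnot6l calls were lost at both days, and that of Gigyf2 at day 3, after division by reads per molecule. The circRNA of Dcbld2 (16:58424561-58433463) fell at day 6 (-0.53 ± 0.14), but did not pass without day 0 replicate 3 (edgeR adjusted p = 0.0739). In a fit of only the 2 groups compared, the calls of Nfkb1 at both days, of Gigyf2 and Cnot6l at day 3 and of Dcbld2 were lost, and no call of Nfix, Nfkb1, Gigyf2, Cnot6l or Dcbld2 reached a fold of 2. Those of Spred2 and Phf21a did not pass at either day.

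For 6 hosts named before the data were examined because circRNAs of these genes have been described in muscle or other cells, the most abundant circRNA did not pass at day 3 or 6. Exon 2 of Zfp609 (9:65794622-65795495) was at 942 ± 474, 1189 ± 453 and 699 ± 210 CPM at days 0, 3 and 6, and exon 2 of Hipk3 (2:104470749-104471847) at 3602 ± 173, 4234 ± 925 and 3695 ± 420 CPM. The log2 fold changes at days 3 and 6 were 0.91 ± 0.60 and 1.07 ± 0.60 for exons 5 to 7 of Qk (17:10213359-10217803) and 0.86 ± 0.34 and 0.84 ± 0.34 for exons 2 and 3 of Bnc2 (4:84546205-84555904). They were -0.21 ± 0.26 and -0.44 ± 0.26 for exon 2 of Cdyl (13:35815909-35816575) and -0.41 ± 0.30 and -0.28 ± 0.30 for exons 2 to 4 of Zfp292 (4:34839332-34839986). In the list of 17 hosts of circRNAs described in muscle, Bnc2 and Ttn rose at day 3 and Svil and Ttn at day 6, and 4 and 5 did when adjusted over the list alone. Its mean was 1.26 at day 3 (median 0.36, camera adjusted p = 0.0011, and adjusted p = 0.079 with an estimated correlation) and 1.12 at day 6 (median 0.46, camera adjusted p = 0.0051, and adjusted p = 0.108 with an estimated correlation). At day 6 the list did not pass without day 0 replicate 1 or day 6 replicate 2 (adjusted p = 0.052 and 0.064), and between days 3 and 6 it did not pass (0.990). Svil did not pass without day 0 replicate 2 or day 6 replicate 2 (edgeR adjusted p = 0.131 and 0.198).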

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

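The comparison of the cell cycle hosts with all other hosts was chosen after the result was seen, and the test after thinning was chosen after the data were seen. The change against day 0 differed between days 3 and 6 for 5 circRNAs and 3 hosts, by the edgeR contrast of day 6 with day 3 itself. The circRNAs of Spag5 (log2 fold change -1.77 ± 0.26) and Zfp516 (-0.81 ± 0.17) were lower at day 6 than at day 3. Those of Cd44, Zbtb38 and Bub1b had no reads at day 6 and were at least 9.02-fold, 8.79-fold and 7.87-fold lower. The host Igsf5 was at least 6.49-fold lower, Spag5 changed by -1.76 ± 0.27 and Pkhd1 by 2.61 ± 0.43. In a fit of only the 2 groups compared, 0 of the 5 circRNAs and 1 of the 3 hosts passed. After division by reads per molecule, 1 of the 5 circRNAs and 2 of the 3 hosts did. The Cd44 circRNA did not pass without day 6 replicate 3 (edgeR adjusted p = 0.0709), nor the host Igsf5 without day 0 replicate 1 or 3 (0.0559 and 0.144). The Zfp516 circRNA did not pass without day 6 replicate 1 or with a minimum fold of 2.

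With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, reached the real count in each comparison. Between days 6 and 3 the real split gave 5 circRNAs and 3 hosts, and the highest of the others gave 1 and 1. For day 3 against day 0 the real split gave 129 circRNAs and 163 hosts against 2 and 0, and for day 6 against day 0 it gave 162 and 233 against 0 and 0 (edgeR).

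Hosts of cell cycle and mitosis were lower at day 6 than at day 3 as a list, with a median log2 fold change of -1.23 (bootstrap 95% interval -2.47 to -0.56) and a mean of -1.69, which was -0.84 without day 3 replicate 1 (camera adjusted p = 0.0053). The lower depth of day 6 replicates 1 and 2 is argued against, as limma's camera gave an adjusted p = 2.2e-04 (3.7e-05 before adjustment) for the list after all libraries were thinned to the smallest total, which evens out reads and not the molecules captured. Dilution by other circRNAs, which would lower all hosts alike, is argued against as the whole cause: with hosts without reads in a group at their bounds, the list median minus that of other hosts was -0.52 (-0.95 to -0.027), and camera gave an adjusted p = 0.024 with an estimated correlation. This criterion replaced, with the values known, 2 others that left dilution open (a list interval below -0.6, or intervals of both medians that do not meet), and the margin was narrow, since at these bounds, which 12 list hosts needed, the median of the list was -0.56 (-0.998 to -0.050) and that of other hosts -0.032 (-0.060 to -0.0031). All these bootstrap intervals resample hosts with the libraries held fixed. They hold neither the spread between libraries nor the correlation between hosts, so they alone cannot decide against dilution. The argument against dilution as the whole cause therefore rests on camera. Fewer linear transcripts of these genes in the later cells may account for the lower counts, and this was not tested, since no linear reads were used here.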

How the results depend on the processing

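Thinning before the tests of circRNAs, hosts and lists, and dividing by reads per molecule, were chosen after the data were seen, and the other alternatives before. The planned test of the circular fraction was not run, as no linear reads were used here, and counting circRNAs from 1 read moved nothing, as no value of 1 occurs. Ratios of the numbers of circRNAs and reads per library moved by less than 1 SD under their alternatives, but some changed sign without 1 library. For circRNAs detected per library, log2 ratio, day 3 against day 0, the value was -0.11 without day 0 replicate 2, and for circRNAs detected per library, log2 ratio, day 6 against day 0, it was 0.023 without day 0 replicate 3 and 0.0054 without day 6 replicate 1. For total back-splice reads per library, log2 ratio, day 6 against day 0, it was -0.26 without day 6 replicate 3, and for total back-splice reads per library, log2 ratio, day 6 against day 3, it was 0.086 and 0.011 without day 6 replicates 1 and 2. DESeq2 called more: 272, 466 and 20 circRNAs and 286, 460 and 19 hosts for day 3 against day 0, day 6 against day 0 and day 6 against day 3. With edgeR these were 129, 162 and 5 circRNAs and 163, 233 and 3 hosts, and the cause was not tested. A fit of only the 2 groups compared called 30, 70 and 0 circRNAs, and 139 and 1 hosts for day 6 against days 0 and 3. Its filter, applied anew, kept 5930, 5419 and 5944 circRNAs against 8153, and what this or the fewer libraries contributed was not told apart. With no filter, 9 circRNAs and 6 hosts differed between days 6 and 3, and 2 circRNAs after division by reads per molecule. Without 1 library the filter was also applied anew and kept 11138 to 11851 circRNAs and 4645 to 4796 hosts, against 8153 and 4135, so that each such value reflects the library and the other set of features together. Leaving out 1 library gave 5 to 8 circRNAs and 2 to 8 hosts between days 6 and 3, with 8 circRNAs without day 3 replicate 2 and 8, 6 and 7 hosts without day 6 replicates 1, 2 and 3. No pairing of libraries by replicate number was seen: same-numbered ones correlated at -0.03 to 0.02 for circRNAs and -0.04 to 0.01 for hosts, and 4 and 1 of 18 lookups found the own number best. A shared culture or batch of same-numbered libraries cannot be excluded by this. The replicate block gave 144, 172 and 5 circRNAs and 188, 259 and 4 hosts. Among lists it ended 2 calls, of myogenic regulators at day 3 (mean log2 fold change 0.17) and DNA replication between days 6 and 3 (-1.02). With an estimated correlation, which leaves the means as they are, the calls of myogenic regulators (0.15 at day 3, 0.26 at day 6), hosts of circRNAs described in muscle (1.26 and 1.12), and, between days 6 and 3, the dystrophin complex (0.83) and DNA replication (-0.996) were lost. The last was also lost after division by reads per molecule (-0.57). Without 1 library the means of called lists ranged from -0.056 to 0.50 for myogenic regulators at day 3 (-0.056 without day 3 replicate 2, lost without day 0 replicate 1) and -0.14 to 0.65 at day 6 (-0.14 without day 6 replicate 3). They ranged from 0.86 to 1.23 for hosts of circRNAs described in muscle at day 6 (lost without day 0 replicate 1 or day 6 replicate 2), and -1.38 to 0.035 for DNA replication between days 6 and 3 (0.035 without day 3 replicate 2, and kept only without day 3 replicate 3). Means of other called lists moved by over 1.5 times for calcium handling at day 3 (1.93 and 2.12 without day 0 replicates 1 and 3), and DNA replication at day 3 (-2.73 without day 3 replicate 2). They did so for the dystrophin complex at day 6 (1.42 without day 0 replicate 3, 0.33 without day 6 replicate 2) and between days 6 and 3 (0.37 without day 6 replicate 2), and the cell cycle between days 6 and 3 (-0.84 without day 3 replicate 1). Division by reads per molecule gave 1.95 and 1.93 for the sarcomere at days 3 and 6 and -0.93 for the cell cycle between days 6 and 3. Other changes of sign were in results past the threshold in neither setting: 125 of 364 values of lists without a call and 9 values of named circRNAs. The other 239 values of these lists kept direction and side of the threshold. Among named circRNAs and hosts, called or not, 2957 values kept both. Another 237 kept direction but lost the threshold, and 31 kept direction and newly passed it. At day 3 the list means by library size were -0.054 for the dystrophin complex, -0.083 for chromatin modifiers and -0.090 for ubiquitin ligases. With the replicate block they were 0.16 for ubiquitin ligases and 0.11 for adipocyte or osteoblast markers. After division by reads per molecule they were -0.036 for energy metabolism, -0.0077 for chromatin modifiers and -0.11 for adipocyte or osteoblast markers, and after thinning -0.017 for ubiquitin ligases. At day 6 they were -0.074 by library size, -0.13 with the replicate block and -0.080 after division for energy metabolism. They were -0.16 with the block for extracellular matrix and 0.13 after thinning for adipocyte or osteoblast markers. Between days 6 and 3 the block gave 0.12 for the sarcomere, -0.29 for energy metabolism and -0.067 for quiescent cells. Division gave -0.075 for quiescent cells, and thinning -0.045 for quiescent cells and 0.47 for adipocyte or osteoblast markers. DESeq2 gave -0.022 for the Hipk3 circRNA at day 6 and -0.065 for that of Phf21a at day 3, and upper-quartile factors gave 0.00076 for the circRNA of Phf21a at 92214049, day 6 against day 0. Without 1 library the means at day 3 ranged from -0.21 to 0.64 for the dystrophin complex, -0.17 to 0.83 for energy metabolism, -0.18 to 0.56 for chromatin modifiers, -0.26 to 0.19 for ubiquitin ligases. They ranged from -0.76 to 0.17 for splicing factors, -0.85 to 0.58 for extracellular matrix, -0.66 to 0.10 for quiescent cells and -0.52 to 0.32 for adipocyte or osteoblast markers. At day 6 they ranged from -0.71 to 0.35 for energy metabolism, -0.55 to 0.32 for chromatin modifiers, -0.53 to 0.10 for ubiquitin ligases, and from -0.64 to 1.02 for extracellular matrix, -0.88 to 0.34 for quiescent cells and -1.37 to 0.52 for adipocyte or osteoblast markers. Between days 6 and 3 they ranged from -0.54 to 0.58 for the sarcomere, -0.46 to 0.50 for calcium handling, -0.27 to 0.37 for myogenic regulators, -0.65 to -0.10 for energy metabolism (where the direction of the test turned). They ranged from -0.58 to 0.12 for ubiquitin ligases, -0.31 to 1.15 for extracellular matrix, -0.46 to 0.54 for quiescent cells, -1.20 to 0.44 for adipocyte or osteoblast markers and -0.40 to 0.20 for hosts of circRNAs described in muscle. For circRNAs the log2 fold change ranged from -0.033 to 0.70 for Zfp609 at day 3, and at day 6 from -0.051 to 0.14 for Hipk3, -0.48 to 0.027 for Zfp292 and -0.10 to 0.14 for Phf21a. Of 140 calls of named circRNAs and hosts, which include all called hosts of the lists, 0 changed sign, 101 passed without each library and 39 were lost without at least 1. The circRNA of Zfp516 is not among these 140. In a fit of only the 2 groups 40 of the 139 that could be refitted were lost. Of all 140, 14 were lost after division by reads per molecule, 17 with a minimum count of 10 and 11 with a minimum fold of 2. DESeq2 ended 12, the block 7, no filter 7, thinning 6, and library size and upper-quartile factors 4 each. Of calls at both days against day 0, 109 circRNAs and 136 hosts with TMM factors were 115 and 115 by library size. Depth and the spread between libraries limit small changes most. In simulated data, 1.49% of 2-fold changes, drawn from the circRNAs with the most reads, were recovered at day 6.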

Other observations

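Of the tests weighed here, those of variance over mean, of exon edges, of the share of increases with DESeq2 and of the share of increases after thinning were chosen after the results were seen. Chromatin, ubiquitin and RNA-binding hosts changed singly, in lists that did not pass as a whole by camera. Of 69 chromatin modifiers, Ezh2 (log2 fold change -1.71 ± 0.35 at day 3 and -1.66 ± 0.35 at day 6, or -2.31 at day 3 without day 3 replicate 2) and Nsd2 (-1.16 ± 0.26 and -1.69 ± 0.26), both histone methyltransferase genes, fell at both days. Kat6b (1.13 ± 0.25), an acetyltransferase gene, and Ncoa2 (1.21 ± 0.36) rose at day 3. Ncoa2 did not pass without day 0 replicate 2 or 3, any 1 day 3 library or day 6 replicate 3 (edgeR adjusted p of 0.0741 to 0.198). It did not pass by library size, with no filter, a replicate block or only 2 groups, or after thinning or division by reads per molecule either. The list had camera adjusted p = 0.716, 0.944 and 0.206 for day 3 against day 0, day 6 against day 0 and day 6 against day 3. With fry the chromatin list passed for day 6 against day 3 (adjusted p = 0.020). Of 50 ubiquitin ligases, Nedd4 fell from 2158 ± 369 to 1060 ± 153 and 894 ± 78.7 CPM and Ubr3 rose at day 6 (1.09 ± 0.26), with camera adjusted p = 0.990, 0.787 and 0.604. Of 31 splicing and RNA-binding factors, Rbm20, a splicing factor gene of titin transcripts, rose from 1554 ± 340 to 3284 ± 528 and 3452 ± 294 CPM. Srpk2, an SR protein kinase gene, rose (1.02 ± 0.18 and 1.05 ± 0.18). Hnrnpll fell (-1.34 ± 0.32 and -1.29 ± 0.32), and the list had camera adjusted p = 0.925, 0.716 and 0.787. Hnrnpll did not pass at day 3 without day 0 replicate 1 or day 3 replicate 1 (edgeR adjusted p = 0.0590 and 0.0947), or at day 6 without day 0 replicate 1 (0.0656). Of 30 matrix hosts, Ltbp1, which encodes a TGF-beta binding protein, fell from 3152 ± 198 to 1350 ± 340 and 1171 ± 212 CPM, and Fn1 rose at day 3 (1.39 ± 0.34) but did not pass without day 3 replicate 2 (edgeR adjusted p = 0.0590), with camera adjusted p = 0.40, 0.990 and 0.255. Adjusted over the list alone, the same numbers passed among chromatin modifiers, RNA-binding factors and matrix hosts, except 1 higher and 2 lower matrix hosts at day 3. Nedd4 at both days and Ubr3 at day 6 passed as well.

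Hosts of energy metabolism (19), quiescent or reserve cells (9) and adipocyte or osteoblast markers (12) gave 0 calls in each comparison, also when adjusted over the list alone (edgeR; 556, 722 and 246 of all hosts had an unadjusted p below 0.05, and DESeq2 called 286, 460 and 19 of all hosts). Camera adjusted p-values were 0.990 in all 3 comparisons for energy metabolism and for adipocyte or osteoblast markers, and 0.787, 0.683 and 0.845 for quiescent cells. Mean, median and test of energy metabolism differed in sign at day 3 (mean 0.24, median -0.02, downward), at day 6 (0.02, -0.11, upward) and between days 6 and 3 (-0.21, -0.06, upward). The same held at day 3 for ubiquitin ligases (0.04, -0.20, downward), quiescent cells (0.23, -0.01, upward) and adipocyte or osteoblast markers (-0.18, 0.26, downward). Of 11 Ttn circRNAs tested, 3 rose at day 3 and 4 at day 6, and the one of exons 123 to 127 held 81.5% of Ttn reads at day 6. Ccdc141, a neighbour of Ttn on chromosome 2, also had 4 called circRNAs at day 6. Among hosts with called circRNAs, 15 of 112 at day 3 and 20 of 136 at day 6 had at least 2, and Agap1 at day 3 and Samd4 at day 6 had calls in both directions. All 23 Pkhd1 circRNAs were exonic and on the strand of the gene.

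circRNAs listed in a single library carried a median of 9 reads, although 2 reads were enough to be listed. Of these, 72.9% had both ends at annotated exon edges. Unless the caller favoured such edges, this argues against alignments misplaced without regard to exons as the main source. That share was below the 94.4% of circRNAs listed in all 9 libraries. False junctions between exons would give such ends too. The caller and its use of the annotation are not known, so such junctions stay open and the share alone cannot settle misplaced alignments. Several reads per molecule may account for the pattern: the mean variance over mean of same-day libraries was 10.1 on the lowest of the 3 days for circRNAs with 20 to 200 reads (medians of 6.82 to 9.19 over the days), and where the other 8 libraries gave 10 to 20 expected reads, 33.5% of values were 0 (26.6% to 43.3% over libraries). Independent reads would give 5.8e-04% and 10 reads per molecule 24.5%. No biological explanation was tested, and differences between cultures that would also spread the counts stay open.

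circRNAs called against day 0 were mostly increases, 82.9% at day 3 and 74.1% at day 6. For circRNAs, scaling by TMM as the whole cause is argued against, as library size alone gave 70.4% at the lower of both days. Lower sequencing depth at day 0 is argued against too, as 72.6% of calls were increases at day 6 and 80.6% at day 3 after all libraries were thinned to the smallest total. The scaling and test of DESeq2 gave 62.5% at day 3 and 58.4% at day 6, so that the size of the excess cannot be told apart from the choice of tool. For hosts, library size alone gave 67.1% at day 3 and 57.6% at day 6, so there the share depended on the scaling. Division by reads per molecule gave 70.3% and 69.2% for circRNAs and 59.6% and 55.6% for hosts. Fewer molecules captured at day 0, which thinning reads does not even out, or a higher output of circRNAs in differentiating cells may also raise the share, and neither was tested, as the counts are relative to the total of each library.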
